A study of Mus musculus with 12 samples.

How the data were processed

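H3K9/14ac was measured by RELACS, a ChIP-seq protocol in which the chromatin of each sample receives its own barcode inside the nuclei before samples are pooled. The labels give 12 samples: 3 WT and 3 KO ChIP libraries and 3 WT and 3 KO input libraries, and 5 µg of antibody was used per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 2.8, Bowtie2 2.3.5.1, deepTools 3.3.2 and MACS2 2.2.6, and the builds mm10 and GRCm38. The program and library scaling behind the differential table, and whether input served as the control for peaks, are not given in the sources used here.

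The deposited files are 12 peak lists, 2 per ChIP library, called per library and not on pooled samples, a differential table and a list of its significant regions. One list per library was called on paired-end fragments, which was used throughout, and the other on single reads. In the peak lists the authors give each peak a score, a fold enrichment (a linear ratio) and -log10 p-value and q-value columns, in the MACS2 layout. The fold and p of a peak are the authors' own and were used to rank, filter or describe peaks and to recover depth, as given below. The lowest -log10 q in the deposited lists is 3.00. The authors' deposited table holds, for 40909 regions built of 150 bp windows, a log2 fold change of the best window, a p-value, an FDR and counts of windows going up and down. It gives no value per library, so no test was refitted and no library could be left out of it. The deposited score of a significant region is -10 times log10 of its FDR, and the listed regions are those with an FDR under 0.05.

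Spans of the 24128 listed regions were taken from the list. For others, the windows overlapping peaks of the 6 single-read lists were joined, which rebuilt 98.8% of the listed spans exactly. That gave 16572 spans, 207 regions were placed by their best window, and 2 regions were not located. Libraries counted as present in a region on an overlap of at least 1 bp.

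Genes are the 21887 protein-coding genes of the GRCm38.p6 annotation, which matches the build in the processing notes. The annotation used gives gene spans without strand, exons or introns, so a promoter region, planned as within 2 kb of a start, became a region within 2 kb of either end of the gene span, and the planned 5 kb upstream became 5 kb to each side. A gene was represented by its region of lowest FDR. This choice favours changed regions, and a region can belong to several genes. No genome was used here, so the planned motif test was not run. Of 357 list entries in the 16 gene lists, 356 matched the annotation.

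Depth was recovered from the lists. In MACS2 a peak's fold is (height + 1) / (background + 1) and its p is the Poisson upper tail, so height and background can be solved for. The lowest background shared by at least 50 peaks was taken as the mean coverage. Heights were recovered within 0.01 of the deposited -log10 p for 97.6% to 99.4% of peaks per library. Tested on simulated data, 100% of 315 peaks returned their height. To read the authors' scaling, the log2 fold change of the best window was set against the log2 ratio of recovered heights in 1245 regions with a summit within 150 bp in every library. The correlation across regions, which are not independent replicates, was 0.993, with an offset of 0.49 against a log2 coverage ratio of -0.78. Counting error of fragments is not included in these values.

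Library measures were compared by two-sided exact permutation tests of the difference in means. These reach no p below 0.1 with 3 libraries per genotype. Exclusive regions were counted for the real split and the 9 other splits of the 6 libraries into equal groups. Gene lists were tested by two-sided Fisher's exact tests against all other tested genes, adjusted by Benjamini-Hochberg over 32 tests. The median of each list was tested by a two-sided permutation test with 100000 draws of genes matched in 5 bins of region width, adjusted over lists with at least 3 genes. Tested on simulated data with 11627 genes, 3 of 40 lists of 25 genes without a shift had a permutation p under 0.05. A simulated list lowered by 0.5 was recovered at a shift of -0.39 (permutation p = 2e-04). Location and neighbourhood were tested by two-sided Fisher's exact tests.

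The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Slc2a3, Il17a, Il17f, Il2, Ifng, Foxp3, Acly, Slc2a1 and Actb. It adds the 8 lowest and 8 highest genes past an FDR of 0.05, leaving out symbols of the form Gm plus digits and those ending in Rik. It also adds up to 4 changed members per list by lowest FDR, and the 5 genes with the most changed base pairs in each direction. Some genes the rule takes are not reported here. Set against these choices were single-read peaks, peaks with -log10 q of at least 5, equal numbers of the 39264 strongest peaks, leaving out each library, a replicate block, 50% coverage, presence in at least 2 libraries, an FDR of 0.01, a fold limit, autosomes only, 1 kb around gene ends, gene bodies, means over regions, no width matching and 5 Mb around Slc2a3. Coverage scaling, the widest region per gene and equal numbers of peaks for exclusive regions were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.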

Results

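The series profiled acetylation of histone H3 at lysines 9 and 14 (H3K9/14ac), a mark of active promoters and enhancers, in mouse T helper 17 (Th17) cells with or without the glucose transporter GLUT3, which is encoded by Slc2a3. Naive CD4 T cells of C57BL/6 mice were differentiated in culture for 3 days and restimulated for 3 h with PMA and ionomycin. The wild type (WT) was compared with cells whose Slc2a3 allele is floxed and deleted by Cd4-cre (KO), with 3 ChIP libraries per genotype. All 6 ChIP samples were barcoded and pooled into a single immunoprecipitation (RELACS). The 6 input libraries were not used here. The labels do not say whether libraries of one genotype came from separate mice, so p-values of library measures reflect a spread that may be technical. The same limit holds for the FDRs of the authors' deposited table. KO replicate 3 alone had peaks on chromosome Y and had 0 over Xist, so the KO libraries may not all come from the same animals. Whether this affects the values of X-linked genes, such as Pdha1, Pgk1 and Foxp3, was not tested. Tests of gene lists, location and neighbourhood take genes or regions as units, which are not independent replicates. Mean fragment coverage, recovered from the peak lists, was 3.99, 3.48 and 2.97 in WT replicates 1 to 3, and 1.85, 2.29 and 1.92 in KO replicates 1 to 3. The KO mean was 0.58 of the WT mean, with no overlap (exact permutation p = 0.1, two-sided, n = 3 per genotype, the smallest p this design allows).

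The targeted gene was examined first. A fall there is only a weak check of the labels, since 18934 of all 40909 tested regions were called lower in KO. Slc2a3 (chromosome 6, 122727809 to 122802363, GRCm38) lost acetylation along its span. Of 9 tested regions over the gene or within 5 kb, 8 were lower in KO and 0 were higher in the authors' deposited table. The region at one gene end (122800501 to 122802600) had a log2 fold change of -1.80 (FDR 8.24e-18) in the authors' deposited table, with a peak in 3 of 3 WT and 3 of 3 KO libraries. The steepest fall over the gene was -1.97, at 122762401 to 122765100, in the authors' deposited table. At 3 of the 9 regions every WT library and no KO library had a peak. Peaks over the gene and 5 kb to each side covered 12507, 12443 and 12461 bp in the WT libraries and 3822, 5427 and 6128 bp in the KO libraries. The neighbourhood did not stand apart: 60.3% of regions within 10 Mb of Slc2a3 were changed against 58.8% of the rest of the chromosome (odds ratio 1.06, Fisher's exact p = 0.588, two-sided). The floxed part of the gene is not given in the sources used here, and loss of the exons themselves was not measured here.

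**Figure D1:**
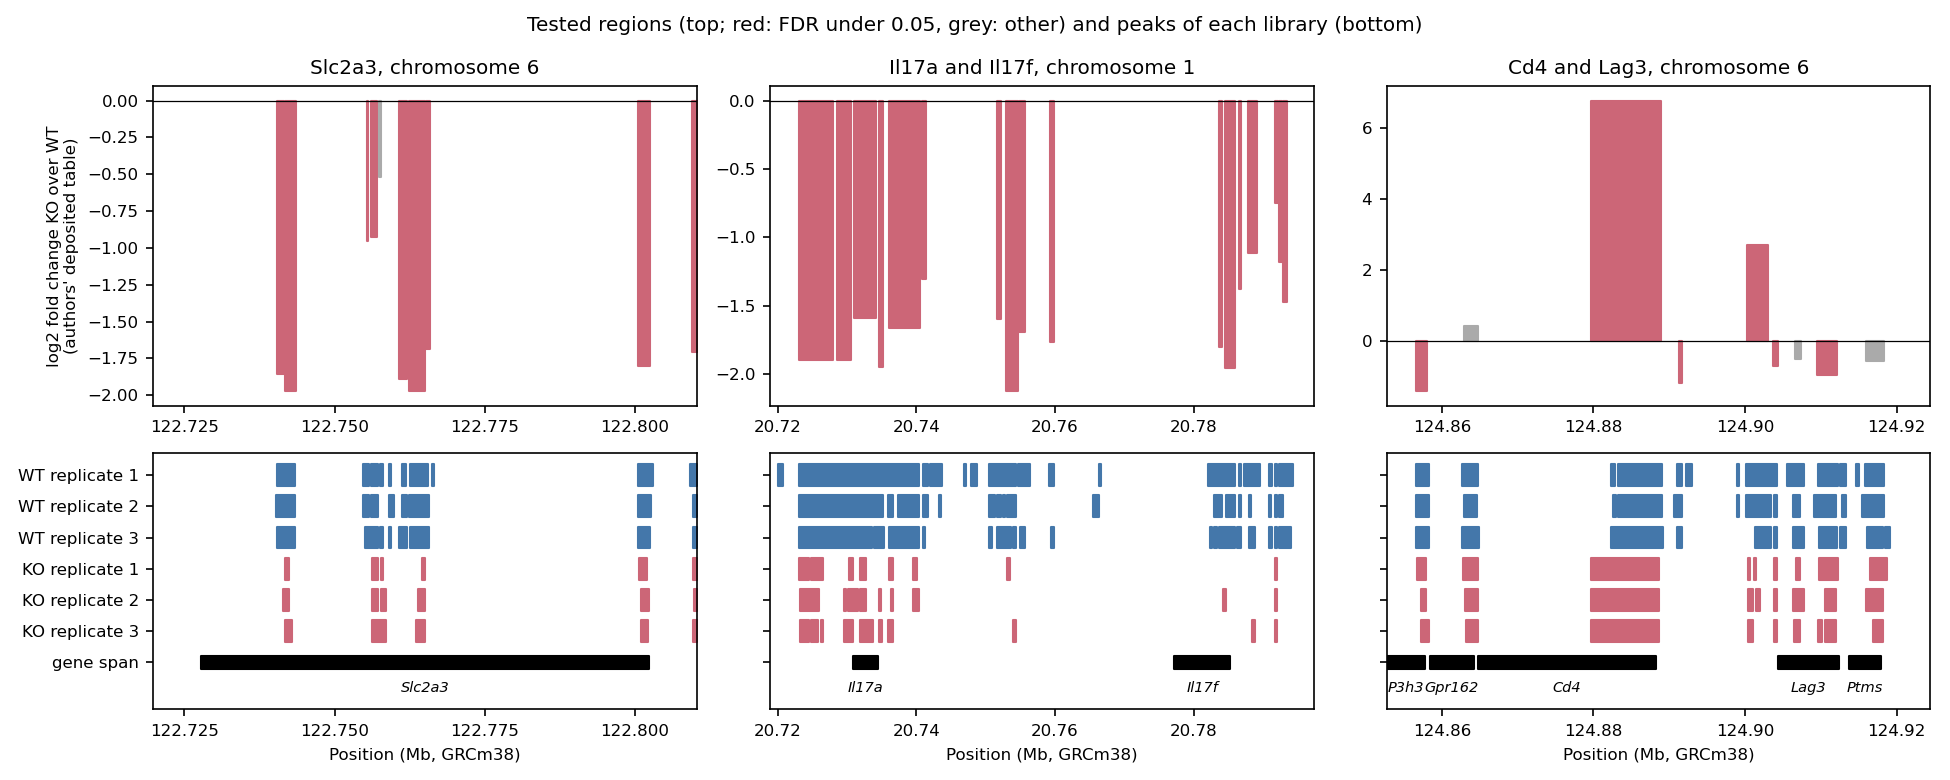
Tested regions of the authors' deposited table (top; height, log2 fold change KO over WT; red, FDR under 0.05; vertical scales differ) and the peaks of each of the 6 libraries (bottom; blue WT, red KO) over Slc2a3, the Il17a and Il17f locus, and Cd4 with Lag3; the horizontal axis is the position in Mb. The Slc2a3 and Il17 regions lie below 0, and the Cd4 block reaches 6.77.

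The loss was broad. In the authors' deposited table, 24128 of 40909 tested regions passed an FDR of 0.05, and 18934 of them (78.5%) were lower and 5194 higher in KO. The median log2 fold change was -0.62 over all tested regions and -0.95 over changed regions of the authors' deposited table. Negative values stood for lower acetylation in KO, which was settled from the peak lists. Of 2730 regions with a peak in 3 of 3 WT and 0 of 3 KO libraries, 99.9% had a negative fold change, and of 1063 regions with the opposite pattern 99.5% had a positive one, in the authors' deposited table. With an absolute log2 fold change of at least 1, 11006 regions were lower and 3023 higher in the authors' deposited table. The split depended on library scaling. Scaling by mean coverage would add 0.29 to every log2 fold change, and at that scale 6183 changed regions were lower by at least 1 and 4723 (43.3%) were higher by at least 1.

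Most genes fell at their ends, by a measure that favours changed regions and so does not compare with the values over all regions. Of 11627 protein-coding genes with a tested region within 2 kb of either end, 7478 (64.3%) were lower and 744 (6.40%) higher by their region of lowest FDR in the authors' deposited table. The median over these genes was -0.81 in the authors' deposited table, and -0.52 at coverage scaling, so gene groups were set against random genes. In Fisher's exact tests of lower and higher members of the 16 gene lists against other genes, 0 of 32 tests had an adjusted p under 0.05 and 3 had an unadjusted p under 0.05. The lowest adjusted p was 0.324, for the interferon response list in both directions.

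Th17 lineage and effector genes lost acetylation more deeply than random genes when each gene was represented by its region of lowest FDR. Il17a and Il17f, which encode the signature cytokines of these cells, were lower at all 5 and all 4 of their tested regions in the authors' deposited table, with log2 fold changes of -1.59 to -1.95 at Il17a and -1.11 to -1.95 at Il17f. Peaks over Il17f and 5 kb to each side covered 6458, 3013 and 4536 bp in the WT libraries and 0, 423 and 436 bp in the KO libraries. Il23r, the receptor subunit for IL-23, had -2.17, the transcription factor Stat3 -2.15 and Hif1a -1.94 in the authors' deposited table. Stat3 had 1 gene-end region, but the mean over gene-end regions was -0.99 for Il23r (6 regions) and -1.37 for Hif1a (2 regions). Over the list of Th17 lineage and effector genes, 16 of 22 tested members were lower and 2 were higher in the authors' deposited table, the same counts as when adjusted over the list alone. The members that rose were Ccl20, a chemokine, with 1.29, and the transcription factor Maf, with 1.11 in the authors' deposited table (both singled out after their values were seen). The share of lower members (72.7%) did not differ from other genes (64.3%; Fisher's exact test, Benjamini-Hochberg adjusted p = 0.818). The list median of -1.44 in the authors' deposited table lay 0.58 below width-matched random lists (permutation p = 2e-05, adjusted p = 0.0003). That shift rests on the choice of 1 region per gene: with the mean over each gene's end regions it was -0.12 (permutation, adjusted p = 0.379).

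Genes of glucose uptake and glycolysis also fell. Of 24 tested members, 20 were lower and 2 higher in the authors' deposited table, or 21 and 2 adjusted over the list alone. The lower members include the targeted gene Slc2a3 itself, with -1.80 in the authors' deposited table. It also enters the list median, and the tests were not run without it. Lactate dehydrogenase genes Ldhb and Ldha had log2 fold changes of -2.08 and -1.77, and the phosphofructokinase gene Pfkp had -1.40, in the authors' deposited table. The members that rose were Pgk1, with 1.28, and Tpi1, with 1.05, in the authors' deposited table (named after their values were seen; the Tpi1 region lies within 100 kb of the changed Cd4 block). Slc2a1, which encodes GLUT1, had -0.47 (FDR 0.506) at its gene end, and 1 of its 4 regions within 5 kb of the gene was lower, with -0.95, in the authors' deposited table. The list median of -1.18 in the authors' deposited table lay 0.34 below random lists (permutation p = 0.00128, adjusted p = 0.0096), while the count of lower members did not pass (Fisher's exact test, adjusted p = 0.447).

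The other metabolic lists did not stand apart from random genes. For acetyl-CoA supply and histone acetylation, 17 of 27 tested members were lower and 0 higher in the authors' deposited table (shift permutation test, adjusted p = 0.626). Its members Slc25a1, the mitochondrial citrate carrier, Pdha1, Hdac7 and Dld had log2 fold changes of -1.48, -1.29, -1.26 and -1.19 in the authors' deposited table. Acly, which makes cytosolic acetyl-CoA from citrate, had -0.61 (FDR 0.0349) at its gene-end region in the authors' deposited table, which was not called at an FDR of 0.01. Over Acly and 5 kb to each side, 3 of 6 regions were lower in the authors' deposited table, and the lowest had -0.86 (FDR 0.00868). For mitochondrial respiration, 18 of 24 were lower and 0 higher in the authors' deposited table (adjusted permutation p = 0.549), led by Ndufs1 (-1.25), Cpt1a (-1.40), Ndufa9 (-1.43) and Ogdh (-1.18). For cholesterol and fatty acid synthesis, 15 of 21 were lower and 0 higher in the authors' deposited table (adjusted permutation p = 0.626), or 16 adjusted over the list alone. The elongase gene Elovl6 had -2.21, the desaturase gene Scd2 -1.51 and Mvd -1.47 in the authors' deposited table.

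**Figure D2:**
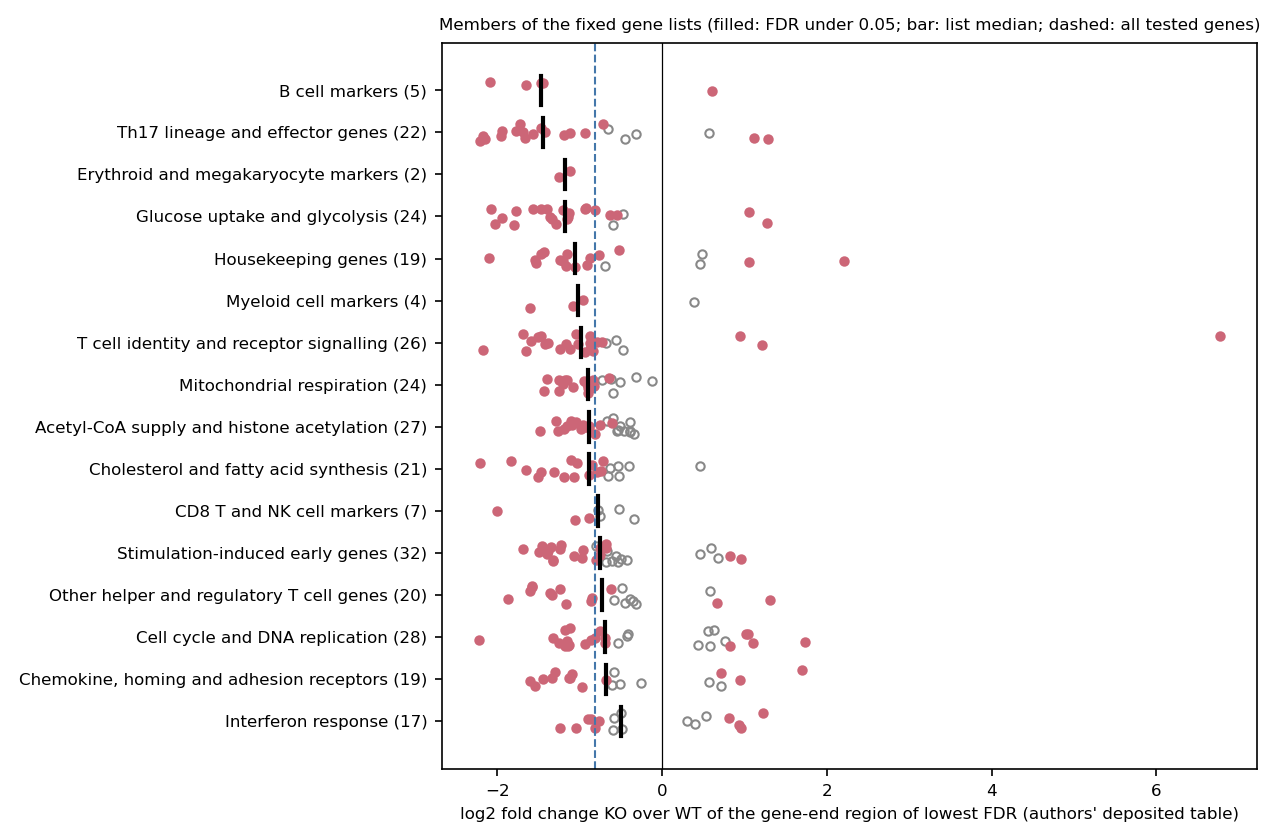
Log2 fold change KO over WT in the authors' deposited table (horizontal axis) of the tested members of the 16 fixed gene lists, each gene by its gene-end region of lowest FDR (filled, FDR under 0.05; black bar, list median; dashed line, median of all tested genes, -0.81). The medians of the Th17 (-1.44) and glycolysis (-1.18) lists lie to the left of that line, and the interferon list (-0.50) to its right. Other medians lie to its left too, such as those of the B cell (-1.47, 5 genes), housekeeping (-1.05) and myeloid (-1.02, 4 genes) lists.

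Genes of T cell identity and activation mostly fell, with exceptions. Of 26 tested T cell identity and receptor signalling genes, 20 were lower and 3 higher in the authors' deposited table (adjusted permutation p = 0.391). Cd247, which encodes the CD3 zeta chain, had -2.18, the kinase gene Zap70 -1.59 and Thy1 -1.42 in the authors' deposited table. The 3 that rose were Cd4, with 6.77, Cd2, with 1.21, and Ptprc, with 0.95, in the authors' deposited table (Cd2 was named after its value was seen). Of 32 stimulation-induced early genes, 19 were lower and 2 higher in the authors' deposited table (adjusted permutation p = 0.373), or 20 and 2 adjusted over the list alone. The activation marker Cd69 had -1.46, Crem -1.39, Junb -1.32 and Nfkbid -1.23 in the authors' deposited table, whereas Dusp1 and Fosb, named after their values were seen, rose by 0.95 and 0.83. Among 20 other helper and regulatory T cell genes, 11 were lower and 2 higher in the authors' deposited table (adjusted permutation p = 0.446). The growth factor gene Il2 was lower at all 5 of its regions, with -1.61 at its gene end, and Cxcr5 had -1.87 and Ctla4 -1.16 in the authors' deposited table. Over gene-end regions the mean was -1.775 for Il2 (3 regions), -1.42 for Cxcr5 (2 regions) and -0.37 for Ctla4 (2 regions). Bcl6, which encodes a repressor known from follicular helper T cells, rose by 1.31 in the authors' deposited table. Foxp3 had no gene-end region, and a region within 5 kb of it had -0.99 (FDR 0.114) in the authors' deposited table. Ifng had 0 tested regions and 0 peaks within 5 kb in every library.

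Cell cycle and interferon genes went both ways. Of 28 cell cycle and DNA replication genes, 15 were lower and 5 higher in the authors' deposited table, or 15 and 6 adjusted over the list alone (adjusted permutation p = 0.363). The cyclin genes Ccnd2, Ccnd3 and Ccne1 had -2.22, -1.32 and -1.18, and Ccnb2 had 1.74, in the authors' deposited table. Over gene-end regions the mean was -1.79 for Ccnd2 (2 regions), -0.54 for Ccnd3 (4 regions) and -1.22 for Ccne1 (2 regions). The Ccnd3 region is shared with Taf8. Of 17 interferon response genes, 6 were lower and 4 higher in the authors' deposited table (adjusted permutation p = 0.127). Ifit2 had -1.24, and Isg15, Gbp3 and Gbp2 had 1.22, 0.93 and 0.81 in the authors' deposited table. Their means over gene-end regions were -1.22 for Ifit2, 0.49 for Isg15 (5 regions), 1.09 for Gbp3 and 0.85 for Gbp2. The Isg15 region is shared with Agrn. With the mean over gene-end regions both lists, and the other helper and regulatory genes, stood above random lists. The shifts were then 0.29, 0.55 and 0.36 (permutation test, adjusted p = 0.00979, 0.0033 and 0.00979). Within 1 kb of a gene end the interferon shift was 0.46 (permutation test, adjusted p = 0.00555). Of 19 chemokine, homing and adhesion receptor genes, 10 were lower and 3 higher in the authors' deposited table, or 11 and 3 adjusted over the list alone (adjusted permutation p = 0.363). Ccr8, the integrin genes Itgb2 and Itgal, and Ccr7 had -1.60, -1.54, -1.31 and -1.34 in the authors' deposited table.

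Housekeeping genes moved with the rest. Of 19 tested members 14 were lower and 2 higher in the authors' deposited table (adjusted permutation p = 0.273). Their median of -1.05 in the authors' deposited table differed by -0.20 from width-matched random lists. Actb had -0.76, Gusb -2.11, Eef1a1 -1.53 and Rpl13a -1.24 in the authors' deposited table. Few marker genes of other cell types had a tested gene-end region. The lower and higher counts in the authors' deposited table were 4 and 1 of 5 B cell genes, 3 and 0 of 7 CD8 T and NK cell genes, 3 and 0 of 4 myeloid genes, and 2 and 0 of 2 erythroid genes. The shift tests gave adjusted permutation p = 0.127 for the B cell, 0.88 for the CD8 T and NK cell and 0.449 for the myeloid list, and the erythroid list was too short to test. The B cell median of -1.47 differed by -0.70 from random lists, further than the Th17 list (-0.58), but over 5 genes. The myeloid median differed by -0.28 and the CD8 T and NK cell median by -0.03. Cd8b1 had -2.00, Blnk -2.09, Spi1 -1.61 and Epor -1.25 in the authors' deposited table. Klrk1 had -1.06 there, but 0.34 as the mean over its 3 gene-end regions.

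Among the gene-end regions of the named genes, the highest log2 fold change was at Cd4. A block of 9300 bp over one end of the gene (chromosome 6, 124879651 to 124888950) had a log2 fold change of 6.77 (FDR 3.44e-168) in the authors' deposited table. A region near Lag3 (124900201 to 124903050) rose by 2.71 in the authors' deposited table, although the other 2 gene-end regions of Lag3 fell, with -0.72 and -0.97, and the mean over all 3 was 0.34. Between the Cd4 block and the higher region near Lag3, the region at 124891351 to 124891650 fell, with -1.18 in the authors' deposited table. KO cells carry Cd4-cre; whether the WT cells carry it is not given in the sources used here. Other genes among the 8 with the highest values in the authors' deposited table were Cdkal1 (3.96), Tnfrsf11b (3.07), Fam110c (2.98) and Rasgef1b (2.71), with a peak in 0 of 3 WT libraries. The mean over gene-end regions was smaller for Cdkal1 (1.52, 2 regions) and Rasgef1b (1.70, 4 regions), while Tnfrsf11b and Fam110c had 1 region each. The Y-linked genes Kdm5d (6.74) and Eif2s3y (6.16) in the authors' deposited table rested on peaks in 1 of 3 KO libraries, KO replicate 3. Among the 8 lowest values in the authors' deposited table were those of the fibrinogen gene Fgg (-4.96), Hormad2 (-3.65), Lad1 (-3.59), Klk8 and Klk9 (-3.11, 1 shared region), Nlrp1a (-3.07) and H2-T-ps (-3.05). Over gene-end regions the mean was -2.37 for Hormad2 (3 regions), -3.42 for Lad1 (2 regions), -1.45 for Klk9 (3 regions) and -2.26 for H2-T-ps (2 regions).

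Several long genes held many changed regions. Among lower regions of the authors' deposited table, Bach2 had 109.5 kb in 17 regions, Inpp4b 107.1 kb in 54, Foxp1 83.9 kb in 38, F13a1 78.6 kb in 48 and Rora 73.2 kb in 55. Rora, which encodes a Th17 transcription factor, fell furthest of these 5, with a median of -2.30 and a lowest value of -4.31 in the authors' deposited table. Among higher regions of the authors' deposited table, Map2k6 had 82.1 kb in 17 regions, Ptprc 52.1 kb in 12, Exoc2 39.8 kb in 12, Myo3b 35.9 kb in 29 and Sox6 35.3 kb in 22, with medians of 1.66, 0.99, 1.04, 1.99 and 2.17.

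Lower and higher regions lay in different places. Regions within 2 kb of a gene end made up 38.4% of lower regions, 15.6% of higher regions and 30.2% of unchanged regions. The odds ratio against unchanged regions was 1.44 for lower regions (Fisher's exact test, adjusted p = 3.09e-60) and 0.43 for higher regions (Fisher's exact test, adjusted p = 6.68e-102). Gene bodies held 30.1% of lower, 49.8% of higher and 40.5% of unchanged regions, with odds ratios of 0.63 and 1.46. Between genes lay 31.5%, 34.5% and 29.4%. Neighbouring regions are not independent, and lower regions were wider (median 1200 bp) than higher and unchanged ones (750 bp), which the test does not match.

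KO libraries had fewer and narrower peaks. The number of peaks was 42425 ± 1290 (SD, n = 3) in WT and 40077 ± 711 (SD, n = 3) in KO. Peaks covered 67.4 ± 2.76 Mb in WT and 55.8 ± 2.40 Mb in KO (SD, n = 3 each), and the mean peak width was 1589 ± 33.0 bp against 1391 ± 47.5 bp. Genes with a peak within 2 kb of an end numbered 11699 ± 36.7 in WT and 11122 ± 30.2 in KO (SD, n = 3 each). No KO library overlapped a WT library in any of these 4 measures (exact permutation p = 0.1 for each, n = 3 per genotype, the smallest possible). Coverage was lower in KO, as given above, and peaks with a summit of at least 20 times the mean coverage were more numerous in KO, at 20880 ± 600 against 18630 ± 420 (SD, n = 3 each).

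**Figure D3:**
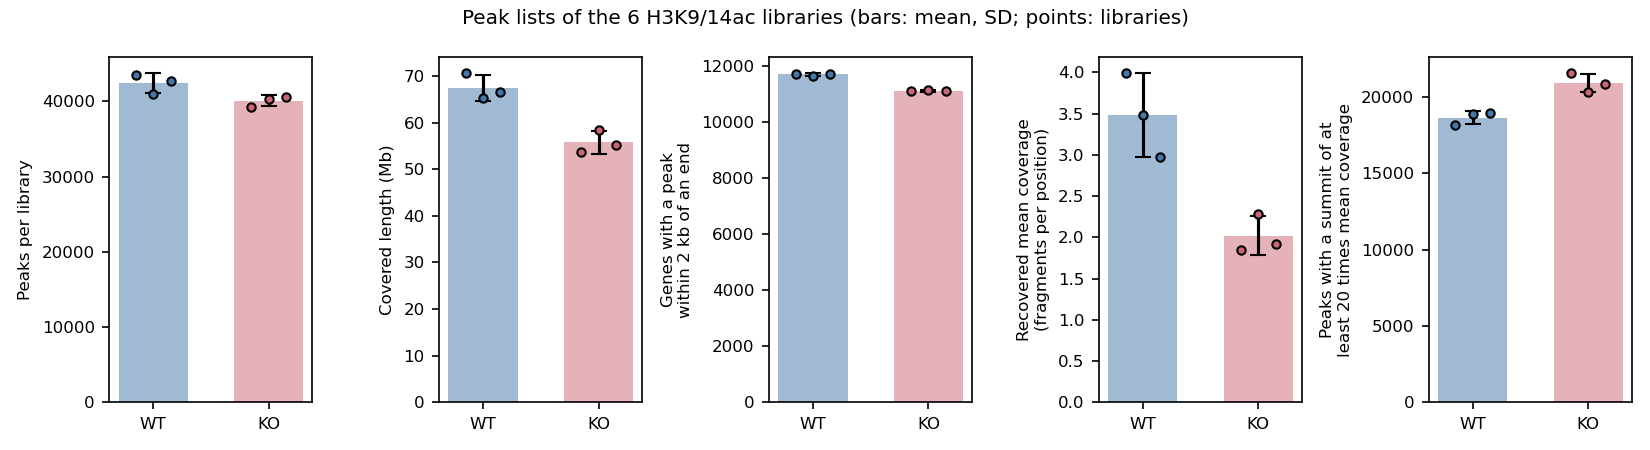
Peaks, covered length (Mb), genes with a peak near an end, recovered mean coverage (fragments per position) and peaks with a summit of at least 20 times that coverage, for 3 WT and 3 KO libraries (bars, mean; error bars, SD; points, libraries). The first 4 measures are lower in KO, with mean coverage at 0.58 of WT, and the last is higher.

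Regions exclusive to one genotype were more often WT regions. Of 56643 merged regions, 20108 (35.5%) had a peak in all 6 libraries, 2856 in 3 of 3 WT and 0 of 3 KO libraries, and 1195 in 3 of 3 KO and 0 of 3 WT libraries. When presence in 2 of 3 libraries sufficed, the counts were 6155 and 3329. With the same number of strongest peaks in every library, a setting added after seeing the data, they were 2352 and 1321. The KO count also rose to 2129 without KO replicate 1 and to 1913 without KO replicate 3. Libraries of one genotype shared more covered bases (Jaccard index 0.739 ± 0.00811 over 3 WT pairs and 0.695 ± 0.00871 over 3 KO pairs, SD) than libraries of different genotypes (0.594 ± 0.00826 over 9 pairs, SD). Coverage did not overlap between the genotypes, so a part of depth in these counts and indices cannot be told apart from genotype.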

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

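Coverage scaling, the widest region per gene and equal numbers of peaks for exclusive regions were chosen after seeing the data. Of 531 alternative values, 513 counted as the same, by rules that differed between results. Library measures needed only the same direction. Counts of regions could move within a set factor, so 4131 WT-only regions, against 2856, counted as the same. Of the 513, 160 were list counts, which passed in no setting. The values of the named genes at coverage scaling say nothing about stability, since a constant shift of this size could not turn them. With an absolute log2 fold change of at least 1, changed regions numbered 11006 lower and 3023 higher, and 6183 and 4723 at coverage scaling, which by construction moves every log2 fold change up by 0.29. Presence in 2 of 3 libraries gave 6155 WT-only and 3329 KO-only regions, a looser rule. Without 1 library in turn the differences were -1807 to -3062 peaks, -10.1 to -13.0 Mb and -564.3 to -598.3 genes. Leaving out 1 library gave 3414 to 4131 WT-only and 1373 to 2129 KO-only regions, as fewer libraries need to share a peak. With the mean over gene-end regions, 4 lists instead of 2 passed the shift test, and the Th17 list, at -0.12, did not; the cause was not tested. Of the named genes Klrk1 turned to 0.34 with that mean, since its other 2 regions lie higher on average, and Kdm5d, Nkg7, Itgax and Acly were not called at an FDR of 0.01. None of the 160 list counts under other settings changed its call; over those settings the lowest adjusted p ranged from 0.171 to 0.486. All 12 alternatives of location kept their call. Same-numbered libraries share only a number: their deviations correlated at 0.00579, 2.81e-04 and 0.00671, and WT replicate 2 correlated best with KO replicate 3. With a replicate block the differences were -2348 peaks, -11.7 Mb and -577 genes (exact sign-flip p = 0.25 each, the smallest 3 pairs allow). The motif test and its alternatives were not run. The differential table could not be refitted without a library. Lower KO coverage limits detection of weak KO peaks.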

Other observations

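The tests of library scaling and of the Cd4 gain were chosen only after the result was seen. Chromosome Y peaks were found in 1 library: KO replicate 3 had 9 peaks on chromosome Y, covering 13415 bp, and the other libraries had 0. KO replicate 3 also had 0 peaks over Xist, against 1 or 2 in each of the other 5 libraries. In the authors' deposited table, 5 of 11 regions on chromosome Y were higher in KO and 0 were lower, where 1 library had peaks. Without chromosomes X and Y and unplaced scaffolds, 18331 regions were lower and 5109 higher in the authors' deposited table. On the unplaced scaffold JH584304.1, 19 of 22 regions were lower and 0 higher in the authors' deposited table.

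Fewer peaks in KO went with lower coverage in every KO library. If depth were the cause, peaks far above the background should be as frequent in KO as in WT, and their KO to WT ratio was 1.12 (20880 against 18630 peaks), while the ratio over all peaks was 0.945. KO had no fewer such peaks, so the bound set for depth was met, but a higher number could not fail it. The test also cannot tell lower depth from a general loss of acetylation. Its threshold is a multiple of each library's own coverage, which a general loss could also lower in a pooled immunoprecipitation. A loss of acetylation, general or at weaker sites, stays open. With the same number of strongest peaks per library, covered length was still lower by 10.5 Mb in KO (difference -10.5 Mb, exact permutation p = 0.1, the smallest for 3 against 3), and peak width too can depend on depth.

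The excess of lower over higher regions may depend on how libraries were scaled. The bound for scaling as the cause, at most 55% lower, was first set on the changed regions, of which 78.5% were lower at both scales, but these were called at the authors' scaling and the shift of 0.29 turned the sign of none. With that share and the 67.8% over all tested regions already seen, the bound was moved to all tested regions with an absolute log2 fold change of at least 1, of which 54.9% were lower at coverage scaling, against 78.4% in the authors' deposited table. That share by itself meets the bound, but so narrowly that, after it was seen, the range over 6 estimates of the shift (0.28 to 0.37) was used instead, and it ran from 47.3% to 56.0%, across the bound. A general loss of acetylation and a difference of scaling therefore cannot be told apart for these regions.

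The gain at Cd4 may come from extra copies of Cd4 DNA in the Cre transgene, which is driven by Cd4 regulatory sequence. The bound, set with the gain in view, was a median below 1 for the surrounding regions, and the 17 other regions within 100 kb had a median log2 fold change of -0.58 in the authors' deposited table (lowest -1.42, highest 2.71, the last near Lag3). Besides the region near Lag3, 3 others of the 17 were higher in the authors' deposited table (0.92, 1.05 at Tpi1, and 1.03), but a region that fell, with -1.42, lies between them and the block, so whether they belong to the same gain was not tested, and the bound was a loose one. Higher acetylation of the native gene stays open, and the input libraries, which would show copy number, were not used here.

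The 6 libraries allow 10 splits into equal groups, too few for a share under 0.05. The real split gave 4051 exclusive regions, the highest of the other splits gave 294, and 1 of the 10 splits, the real one, gave as many. The real split also separates higher from lower coverage, so its count cannot tell genotype from depth.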
